A study of Mus musculus with 21 samples.

How the data were processed

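The series profiled whole testes of wild-type CD-1 mice, an outbred stock, on single-channel oligonucleotide arrays. Per the labels' protocols, mice were time-mated within a short window, gonads were excised whole at gestation days (gd) 11, 12, 14, 16 and 18 and at postnatal day (pnd) 2, and the tissue was snap frozen. Per the labels, total RNA was isolated from whole testes and carried a biotin label. The sample labels describe pools of 2 for the gd11 samples, pools of 5 for the gd12 samples and no pooling from gd14 on. They list 5 gd11 arrays and 3 arrays at each later stage. The series' design text instead describes 3 samples at each time, each the testis pair of 1 animal from its own dam. Both statements cannot hold for gd11 and gd12, and the sample labels were followed. With pools, the spread between arrays is that between pools, not between animals. A reference array held RNA of a pool of 8 whole newborns at pnd 0.5, 4 male and 4 female, per the labels.

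The deposited values are intensities per probe set on a linear scale, made by the authors with GCOS (Affymetrix GeneChip Operating Software), per the submitters' processing notes. Its version and algorithm are not given in the sources used here. Read from the values, the mean intensity of each of the 21 arrays, with the lowest and highest 2% of probe sets trimmed, was 500, as a single scaling factor per array gives. Detection calls, scanner images and dates were not used here. No batch is named in the labels, so none could be tested. Replicate numbers run on over the whole series and pair no samples. No pair of arrays held identical values.

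Gene names came from a table of the platform's probe sets, updated through Entrez identifiers against a mouse gene table of assembly GRCm38.p6, which was used for names only. Of 45101 probe sets, 34945 carried 1 gene, 932 several and 9160 none, and 64 were control probe sets. Of the 34945, 34741 matched through the Entrez identifier and 204 kept the platform's symbol. No symbol changed. Probe sets with several genes or none were left out of gene tests and named nothing. The genome build behind the authors' probe sets is not given in the sources used here, and no coordinates are printed.

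The values were used as deposited, because the trimmed means matched within the limit of 5% set beforehand, and were transformed to log2(intensity + 22.4), where 22.4 is the 20th percentile of all testis values. A fold change on this scale understates the change of dim genes. Probe sets were kept when they lay above their array's 40th percentile on at least 3 of the 20 testis arrays. Each gene was represented by its probe set with the highest mean log2 value over the 20 arrays, chosen without regard to stage. This left 14338 genes. A stage mean below 71.6, the 40th percentile of all testis values, is called near background in the text.

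All 20 testis arrays entered 1 limma fit with 6 stage means (lmFit and eBayes with an intensity trend, 14 residual and 4.94 prior degrees of freedom). The fit holds 1 spread per gene for all stages, so a gene that varied at 1 stage is less readily called at the others. In comparisons with the stage where it varied, such a gene is more readily called than its spread there allows. The comparisons were the 5 adjacent stage pairs and pnd2 against gd11, with Benjamini-Hochberg adjustment over all genes within a comparison and a call at an adjusted p below 0.05. A moderated F-test over the 6 stages used the same adjustment. The comparison of pnd2 with gd11 shares its arrays with adjacent comparisons and is not independent of them. The reference array has no replicate and entered no test: per gene, the log2 difference between the pnd2 mean and the reference is given, and a gene list's median difference was placed among 10000 random lists of the same size matched on mean expression.

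Before the data were examined, 30 gene lists were fixed from textbook knowledge. They cover early gonad and sex determination, Sertoli cells, fetal Leydig cells and steroidogenesis, cholesterol synthesis, pluripotency and primordial germ cells, fetal male germ cells and the piRNA pathway, meiosis, spermatogonia, ovary and pre-granulosa cells, interstitial and stromal progenitors, peritubular myoid cells and smooth muscle, endothelium, cell division, cell cycle inhibitors, Hox genes, retinoic acid, hedgehog signalling, basement membrane and matrix, imprinted genes, hormone receptors, and glutathione and detoxification. Markers of other cells that a dissection could hold were erythroid cells, macrophages and leukocytes, mesonephros and duct epithelium, adrenal cortex and medulla, skeletal and cardiac muscle, liver and neural tissue. A list of X- and Y-linked genes and a list of immediate early and stress genes served as checks. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 180 tests of 30 lists in 6 comparisons, and again with an estimated correlation. Of the 71 shifts called at the preset correlation, 1 held with an estimated correlation, that of the Sertoli list from gd11 to gd12. The rotation test fry, which asks whether a list's genes move one way on balance, called 57.

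The genes named in the text followed a rule fixed before the data were examined. Per comparison it took the 6 largest rises and 6 largest falls among called genes whose stage ranges did not overlap and whose brighter stage mean exceeded 123.4, the median of all values, and it skipped clone-like names. For each list described it took up to 4 called members with the largest changes. It also held 20 genes by name whatever their p, of which 15 were measured here. Array values of single genes were chosen after they were seen.

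Alternatives fixed in advance were pseudocounts at the 5th and 40th percentiles (3.92 and 71.6), quantile normalization, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, a variance prior without trend, array weights, a fit of only the stages compared, a threshold of at least 2-fold, and leaving out each array in turn. Leaving out arrays that stood apart was added after the data were examined. The statistical steps were tested on simulated data, drawn from the real means and spreads for the 14338 genes with 200 changed by known folds. Fewer genes were changed there than were called in any comparison of the real data. The recovery and false calls given below therefore describe the simulated data only. R 4.3.3 and limma 3.58.1 were used. The number of arrays limits the precision of every value.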

Results

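Transcript levels were measured in whole testes of CD-1 mice from gd11 to pnd2, a series through testis formation and the end of fetal life. The 20 testis arrays comprised 5 from gd11 (Theiler stage 18), and 3 each from gd12 (stage 20), gd14 (stage 22), gd16 (stage 24), gd18 (stage 26) and pnd2 (stage 27). Arrays of gd11 were made from pools of 2, those of gd12 from pools of 5, and later arrays from single animals. A further array held RNA of 8 whole newborns. The number of arrays limits the precision of each value. Intensities are given as mean ± SD over the arrays of a stage (n = 5 at gd11, n = 3 at every other stage), and changes as log2 differences of log2(intensity + 22.4) with the limma standard error (SE) and adjusted p. Pearson correlations were taken over all probe sets except controls, unfiltered, which are not independent replicates. They ranged from 0.934 to 0.972 between gd11 arrays and from 0.965 to 0.979 within the other stages. Between adjacent stages the mean correlation was 0.942, 0.952, 0.962, 0.965 and 0.964, and between gd11 and pnd2 it was 0.908. The ratio of 3' to 5' signal of the beta-actin control probe sets, a measure of RNA integrity, was 1.19 to 1.29 at gd11 and 1.27 to 1.42 on the other testis arrays. That of the Gapdh control probe sets was 0.72 to 0.81 at gd11 and 0.67 to 0.78 on the others.

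By the moderated F-test, 9790 of 14338 genes (68.3%) varied with stage, and 4661 of these differed at least 2-fold between their highest and lowest stage. Of the 4661, 1032 were highest at gd11 and 1014 at pnd2, against 347 at gd12, 615 at gd14, 878 at gd16 and 775 at gd18. The lowest stage was gd11 for 1875 genes and pnd2 for 1130. Adjacent stages differed by 3067, 2681, 1488, 700 and 1118 genes in order of age, and pnd2 differed from gd11 by 6965. In fits of only the 2 stages compared, the adjacent counts were 1286, 2504, 3020, 1143 and 1632, so their order depended on the fit.

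**Figure D1:**
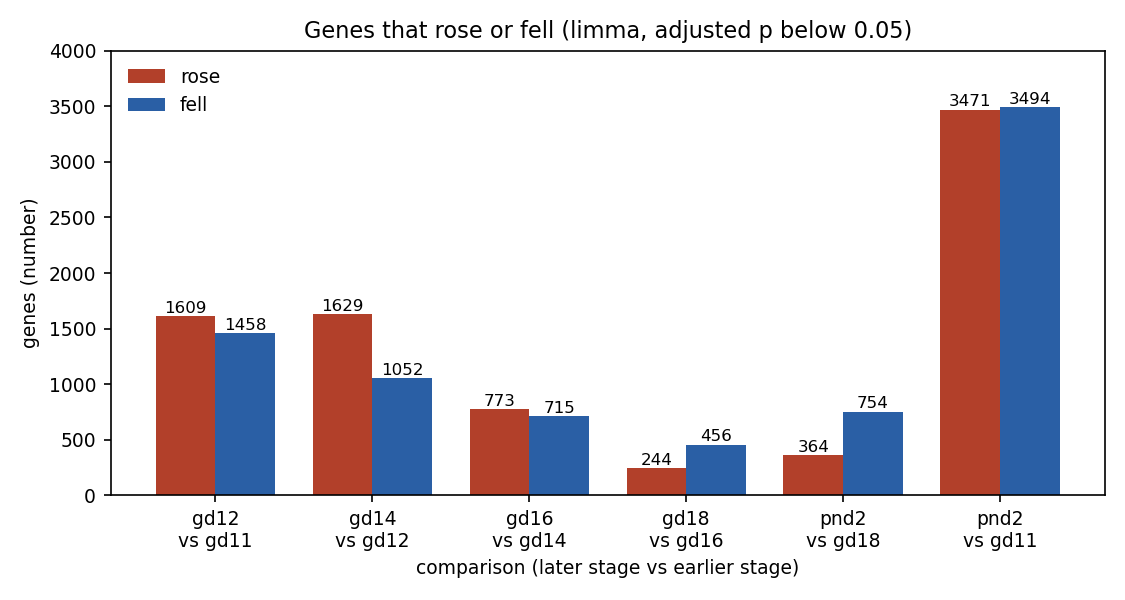
Bars give the number of genes (vertical axis, starting at 0) that rose or fell in each of the 6 comparisons (horizontal axis) at an adjusted p below 0.05 by limma. For gd12 against gd11, where 5 arrays stood against 3, 1609 rose and 1458 fell, and for gd18 against gd16 244 rose and 456 fell.

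From gd11 to gd12 the genes of the Sertoli cell, the somatic cell that forms the testis cords, rose steeply. Amh (probe set 1450573_at), which encodes anti-Müllerian hormone, went from 9.61 ± 11.8, near background, to 998 ± 556 (log2 change 4.89 ± 0.34 SE, adjusted p = 1.39e-08). Dhh (1434959_at), the hedgehog ligand secreted by Sertoli cells, rose from 73.3 ± 22.9 to 2260 ± 752 (4.56 ± 0.18, adjusted p = 7.33e-12). Ptgds (1423859_a_at), encoding a prostaglandin D synthase, rose from 52.3 ± 40.2, near background, to 4200 ± 1610 (5.93 ± 0.33, adjusted p = 6.94e-10). Cst9, a cystatin gene, Defb19, a beta-defensin gene, Tesc, encoding the calcium-binding protein tescalcin, and Col9a3, a collagen IX chain, rose by 5.62 ± 0.48, 5.10 ± 0.31, 4.87 ± 0.29 and 4.79 ± 0.34. Of the 25 measured Sertoli genes, 21 rose, 0 fell and 4 were not called, and 21 rose when adjusted over the list alone. The list's shift had an adjusted p of 1.02e-21 by camera, and adjusted p = 0.0281 with an estimated correlation. Sox9 (1451538_at), the transcription factor that directs Sertoli fate, stood at 912 ± 454 and 819 ± 63.3 (-0.03 ± 0.25, adjusted p = 0.95). Sry, the Y-linked testis-determining gene, fell from 323 ± 96.4 to 114 ± 124 (-1.68 ± 0.45, adjusted p = 0.0125). Its change was -1.13 without gd12 replicate 13 (adjusted p = 0.0902), -1.52 without gd12 replicate 14 (adjusted p = 0.0591) and -2.40 without gd12 replicate 15.

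From gd11 to gd12, in the pluripotency and primordial germ cell list, 22 of 25 measured members rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 1.24e-15 by camera, adjusted p = 0.378 with an estimated correlation). Dppa3, expressed in primordial germ cells, went from 406 ± 122 to 5140 ± 2900 (3.42 ± 0.4). Lefty1, encoding a Nodal antagonist, rose by 3.22 ± 0.47. Pou5f1, the pluripotency factor Oct4, rose by 2.32 ± 0.37. Without gd12 replicate 13, Dppa3 rose by 4.02 and Pou5f1 by 2.91. Among fetal male germ cell and piRNA genes, 15 of 23 rose and 0 fell, and 17 rose adjusted over the list alone (adjusted p = 4.67e-11, adjusted p = 0.378 with an estimated correlation). Dazl, a germ cell RNA-binding protein gene, rose from 302 ± 116 to 6040 ± 2840 (4.16 ± 0.3) and Ddx4, the germ cell helicase gene, by 3.72 ± 0.29. Meiosis genes gave 10 rises and 0 falls among 19 (11 rises adjusted over the list alone) (adjusted p = 1.1e-07, adjusted p = 0.378 with an estimated correlation). Smc1b, a meiotic cohesin subunit, rose by 3.16 ± 0.29 and Syce1, of the synaptonemal complex, by 2.49 ± 0.33. Stra8, the retinoic acid-responsive meiotic gatekeeper, was at 52.8 ± 30.1, near background, and 81.6 ± 70.7 (0.34 ± 0.43, adjusted p = 0.614). Dnmt3l was near background at both stages (10.4 ± 6.43 and 7.94 ± 3.27).

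From gd11 to gd12 Cyp17a1 (1417017_at), the 17-alpha-hydroxylase of androgen synthesis, went from 6.78 ± 2.14, near background, to 378 ± 293 (3.55 ± 0.34, adjusted p = 9.2e-07), and Hsd17b3, which makes testosterone, rose by 2.33 ± 0.25. Hsd3b1 rose by 2.68 ± 0.33, and by 2.04 without gd12 replicate 13. In the fetal Leydig and steroidogenesis list, 7 of 19 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (adjusted p = 0.000313, adjusted p = 0.504 with an estimated correlation). The list's median change of 0.55 was 0.31 without gd12 replicate 13, which stood high in adrenal genes and held the highest gd12 level of this list, and 1.07 without replicate 14. Star, the mitochondrial cholesterol carrier, was at 125 ± 100 and 357 ± 243 (1.5 ± 0.54, adjusted p = 0.055). Of 20 cholesterol synthesis genes, 0 rose and 12 fell, against 14 falls adjusted over the list alone, with Cyp51 at -0.91 ± 0.14 and Mvd at -0.86 ± 0.14 (adjusted p = 1.59e-08, adjusted p = 0.406 with an estimated correlation). Their median change of -0.59 was -0.39 without gd11 replicates 16 and 17. Basement membrane and matrix genes gave 11 rises and 1 fall among 27, with the same counts adjusted over the list alone, led by Fbln2 (2.38 ± 0.33) and the collagen VI chain Col6a1 (2.04 ± 0.25; adjusted p = 0.000141, adjusted p = 0.659 with an estimated correlation). Their median change of 0.41 was 0.07 without gd11 replicates 16 and 17, with 9 rises and 2 falls (list adjusted p = 0.0264). Without gd12 replicates 13 and 14 as well, which leaves 1 gd12 array, it was -0.03. In the early gonad and sex determination list, 9 of 23 rose and 2 fell (10 and 4 adjusted over the list alone), among them Dmrt1 (2.39 ± 0.3) and Nr5a1 (1.88 ± 0.28), both gonadal transcription factors (adjusted p = 0.0221, adjusted p = 0.582 with an estimated correlation). The list's median change of 0.18 was 0.38 without gd11 replicates 16 and 17.

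From gd11 to gd12 Pantr1, a non-coding RNA transcribed beside Pou3f3, went from 1530 ± 1850 to 28 ± 22.2, near background (-4.16 ± 0.7, adjusted p = 0.000337), and by -3.55 without gd11 replicate 16. Mab21l2, Pou3f3, Msx3, Hoxb5os and Tfap2b changed by -3.42 ± 0.5, -3.14 ± 0.42, -3.03 ± 0.73, -3.02 ± 0.4 and -2.93 ± 0.41. At gd11 they stood at 634 ± 381, 1960 ± 1340, 525 ± 612, 2130 ± 1220 and 514 ± 161, so the gd11 arrays differed widely for most of them. Whether gonad or other tissue in the pools gave these falls was not tested. Of 27 measured Hox genes, the regulators of axial position, 17 fell and 0 rose (17 and 1 adjusted over the list alone), for example Hoxa7 (-2.67 ± 0.29) and Hoxb6 (-2.67 ± 0.4; adjusted p = 1.94e-07, adjusted p = 0.406 with an estimated correlation). Among 14 neural genes 7 fell and 0 rose, against 10 falls adjusted over the list alone, with the neurofilament gene Nefl going from 6820 ± 7430 to 509 ± 437 (-3.25 ± 0.77; adjusted p = 0.000283, adjusted p = 0.659 with an estimated correlation). Nefl changed by -3.92 without gd12 replicate 13, and was not called without gd12 replicate 15 (-2.45, adjusted p = 0.0609). All 14 neural genes had their 2 highest gd11 intensities in replicates 16 and 17, where Nefl read 17280 and 12120 against 1611, 914 and 2203 in replicates 18, 19 and 20. Without these arrays the median neural change went from -2.17 to -0.73 and the shift was not called (adjusted p = 0.152). Without gd12 replicates 13 and 14 as well, which leaves 1 gd12 array, the neural median was -1.62. Msx3 lost its call in the fit of gd11 and gd12 alone (adjusted p = 0.0765). Macrophage and leukocyte genes gave 4 falls and 0 rises among 21, also adjusted over the list alone, with Coro1a at -1.42 ± 0.26 (adjusted p = 0.00808, adjusted p = 0.751 with an estimated correlation). Their median change of -0.40 was -0.70 with 7 falls without gd11 replicates 16 and 17, and -0.90 without gd12 replicates 13 and 14 as well, which leaves 1 gd12 array. Of the markers of blood, ducts and adrenal, 1 of 12 erythroid genes fell, Hbb-bh1 (-1.79 ± 0.37), an embryonic beta-like globin. The erythroid shift was called lower without gd12 replicate 14 (median -0.66 against -0.41, adjusted p = 0.0158). Without replicates 13 and 14, which leaves 1 gd12 array, its median was -0.81, and -0.82 without gd11 replicates 16 and 17 as well. On other lists, 6 of 20 mesonephros and duct genes fell and 1 rose, and 0 of 13 adrenal genes were called (adjusted p = 0.113, 0.217 and 0.464). The embryonic globin Hbb-y was not called (34100 ± 2490 and 33500 ± 4000, change -0.03 ± 0.41, adjusted p = 0.969). Its intensity lay near the array maxima (39857 to 50373 at gd11), where a change may be hidden, which was not tested.

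Over all genes, 1609 rose and 1458 fell from gd11 to gd12, 952 of them at least 2-fold (581 rises, 371 falls), and 4931 had an unadjusted p under 0.05. Of the 3067 called genes, 2330 had stage ranges that did not overlap. In the simulation of this comparison, 28.4% of 67 genes changed 1.5-fold, 62.7% of 67 changed 2-fold and 93.9% of 66 changed 4-fold were recovered among 14338 genes, with 3 false calls. The simulation changed 200 genes, against 3067 called here, so recovery and false calls in the real data were not measured. The count was 1671 without gd12 replicate 15 and 1286 when only the arrays of gd11 and gd12 entered the fit. Median and test of the smooth muscle and hedgehog lists differed in sign.

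**Figure D2:**
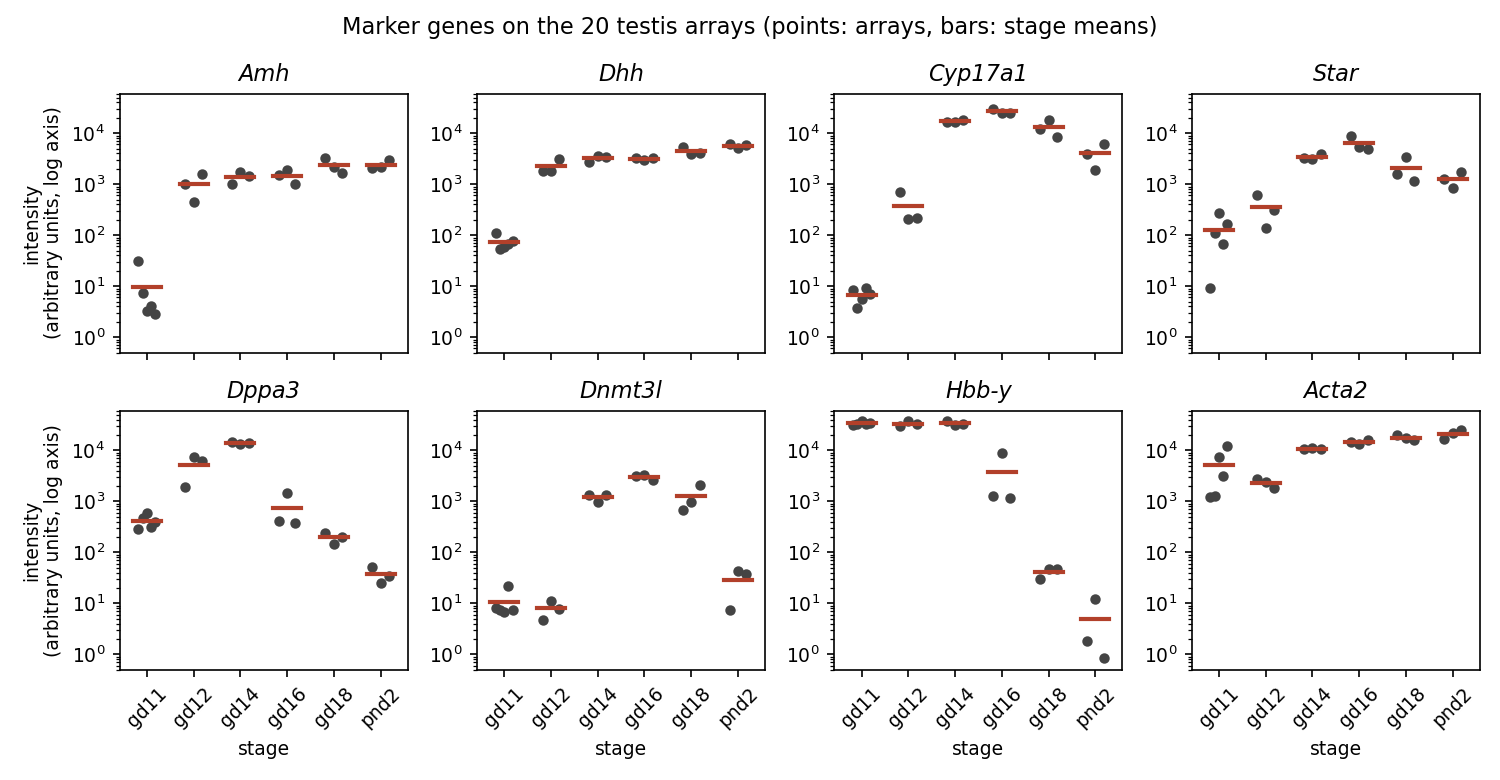
Each panel shows the intensity of 1 gene (vertical log axis, arbitrary units) on the 20 testis arrays by stage (horizontal axis), where points are arrays and bars are stage means. Amh and Dhh rose between gd11 and gd12, Cyp17a1 stood at 17100 ± 765 at gd14 and 26700 ± 2830 at gd16, Dppa3 at 14000 ± 492 at gd14 and Dnmt3l at 2990 ± 324 at gd16. Hbb-y stood at 34100 ± 3470 at gd14 and 4.92 ± 6.22, near background, at pnd2.

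From gd12 to gd14 Gtsf1 (1441836_x_at), needed for piRNA function, went from 69.9 ± 10.8, near background, to 4840 ± 372 (5.72 ± 0.32, adjusted p = 1.96e-09). Dnmt3l (1425035_s_at), the cofactor of de novo DNA methylation in male germ cells, rose from 7.94 ± 3.27, near background, to 1220 ± 221 (5.35 ± 0.33, adjusted p = 7.88e-09), and Nxf2, an X-linked RNA export factor gene, by 5.61 ± 0.35. Cyp17a1 (1417017_at) rose from 378 ± 293 to 17100 ± 765 (5.65 ± 0.38, adjusted p = 2.09e-08). Cyp11a1 (1448804_at), the side-chain cleavage enzyme that starts steroid synthesis, rose from 205 ± 222 to 6300 ± 43.5 (5.25 ± 0.52, adjusted p = 1.63e-06; 6.01 without gd12 replicate 13). Star rose by 3.39 ± 0.6 (adjusted p = 0.000716). Rrad, encoding a Ras-related GTPase, rose by 4.51 ± 0.43.

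Of the 23 measured fetal male germ cell and piRNA genes, 19 rose and 0 fell, also adjusted over the list alone, including Tex101 (4.48 ± 0.34) and Piwil4 (4.15 ± 0.43), the nuclear Piwi protein gene (adjusted p = 3.19e-21, adjusted p = 0.206 with an estimated correlation). Meiosis genes gave 8 rises and 0 falls among 19 (9 rises adjusted over the list alone), with Tex12 at 4.04 ± 0.34 and Tex15 at 2.96 ± 0.34 (adjusted p = 0.000139, adjusted p = 0.504 with an estimated correlation), while Stra8 read 81.6 ± 70.7 and 124 ± 41.5 (adjusted p = 0.356). The meiosis median of 1.09 was 0.62 without gd12 replicate 13, with 5 rises and 1 fall. The pluripotency list was mixed, with 6 rises and 2 falls among 25 (7 and 2 adjusted over the list alone; adjusted p = 0.749). Tdgf1, a Nodal co-receptor gene, went from 116 ± 35.7 to 5.86 ± 1, near background (-2.26 ± 0.32), Dnd1 rose by 2.17 ± 0.37 and Pou5f1 by 1.53 ± 0.41 (adjusted p = 0.0147). Without gd12 replicate 13 the changes of Dnd1 and Pou5f1 were 1.58 and 0.94, the latter not called (adjusted p = 0.0935).

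In the fetal Leydig and steroidogenesis list, 10 of 19 rose and 0 fell, also adjusted over the list alone, among them Agt (3.86 ± 0.36) and Hsd3b1 (3.67 ± 0.37; 4.32 without gd12 replicate 13; adjusted p = 1.13e-06, adjusted p = 0.393 with an estimated correlation). Of 20 cholesterol synthesis genes 18 rose and 0 fell, against 19 rises adjusted over the list alone, with Tm7sf2 at 1.76 ± 0.32 and Dhcr7 at 1.69 ± 0.26 (adjusted p = 6.36e-14, adjusted p = 0.378 with an estimated correlation). Sertoli genes gave 9 rises and 0 falls among 25 (10 rises adjusted over the list alone), with Cst12 at 2.50 ± 0.38 and the inhibin subunit gene Inha at 2.12 ± 0.31 (adjusted p = 0.000357, adjusted p = 0.412 with an estimated correlation). Amh (0.61 ± 0.38, adjusted p = 0.285), Dhh (0.54 ± 0.2, adjusted p = 0.0695) and Sox9 (-0.39 ± 0.28, adjusted p = 0.369) were not called. The smooth muscle actin gene Acta2, a marker of peritubular myoid cells, rose from 2330 ± 487 to 10800 ± 213 (2.23 ± 0.57, adjusted p = 0.0104), with 2 rises and 0 falls among the 17 genes of its list, also adjusted over the list alone (adjusted p = 0.109). Immediate early and stress genes, a check of handling, gave 4 rises and 0 falls among 20 (6 rises adjusted over the list alone; adjusted p = 0.0074, adjusted p = 0.465 with an estimated correlation). Among them Hspa1b went from 702 ± 239 to 3600 ± 425 (2.38 ± 0.25, adjusted p = 3.73e-06). The median change of the list was 0.37, and 0.21 without gd12 replicates 13 and 14, which leaves 1 gd12 array. The check's shift was called here, from gd16 to gd18 and from gd11 to pnd2. Handling that differed between stages therefore stays open and cannot be told apart from stage.

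Of 27 cell division genes, 16 fell and 0 rose from gd12 to gd14, against 21 falls adjusted over the list alone (adjusted p = 6.95e-11, adjusted p = 0.406 with an estimated correlation). Mki67, the Ki-67 proliferation antigen, went from 7380 ± 802 to 4530 ± 358 (-0.70 ± 0.11, adjusted p = 0.000223), and Ccne1, cyclin E, changed by -1.44 ± 0.17. Hox genes gave 14 falls and 0 rises among 27, also adjusted over the list alone (adjusted p = 9.45e-07, adjusted p = 0.443 with an estimated correlation). Hoxa5 changed by -2.48 ± 0.42 and Hoxa9 by -2.40 ± 0.48, or by -3.10 and -3.03 without gd12 replicate 15. Another probe set of each gene was not called by limma (Hoxa5 -0.47, adjusted p = 0.29, and Hoxa9 -0.88, adjusted p = 0.147). For Hoxb3, with -2.31, another probe set changed by -2.08 (adjusted p = 0.00233). Without gd12 replicate 13, 7 Hox genes fell. Without replicates 13 and 14, which leaves 1 gd12 array, the Hox median went from -1.11 to -0.33. Endothelial genes gave 6 falls and 1 rise among 20 (8 and 1 adjusted over the list alone), with Emcn at -1.37 ± 0.28 and Vwf, the rise, at 2.30 ± 0.45 (adjusted p = 0.000165, adjusted p = 0.659 with an estimated correlation). Their falls numbered 2, with 1 rise, without gd12 replicate 13. Without replicates 13 and 14, which leaves 1 gd12 array, their median went from -0.56 to -0.43. Falls were also called for Shisa3 (-3.92 ± 0.72), Foxd1 (-3.41 ± 0.52), a stromal transcription factor gene, Rhox6 (-3.22 ± 0.54), Fabp4 (-3.21 ± 0.56), Hbb-bh1 (-3.05 ± 0.41) and L1td1 (-3.03 ± 0.43). Hbb-y was not called (33500 ± 4000 and 34100 ± 3470, adjusted p = 0.976), again near the array maxima, where a change may be hidden. Of 12 erythroid genes, 2 fell (adjusted p = 0.12).

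Arrays of gd12 stood apart in markers of other tissues, which enters every comparison with gd12. Xist, the X-inactivation transcript of female cells, read 87.7, 2616 and 40.6 on gd12 replicates 13, 14 and 15 and 20.7 to 91.6 on the other testis arrays. The change of its mean was not called (adjusted p = 0.0738 against gd11 and 0.269 against gd14). In replicate 13, Chgb, a chromogranin gene of adrenal medulla and neurons, read 2404 against 239 and 20.3 in replicates 14 and 15, and all 13 adrenal genes measured were highest there among the gd12 arrays. Without replicates 13 and 14, which leaves replicate 15 alone at gd12, the median change of the Sertoli list from gd12 to gd14 was 0.28 against 0.63. Single genes changed by 2.56 (Acta2), -2.68 (Shisa3), -2.11 (Fabp4), -1.05 (Emcn), -1.23 (Hoxa5) and -1.13 (Hoxa9). Leaving out single gd12 arrays moved Foxd1 to -2.82 (replicate 13) and -4.40 (15), Rhox6 to -4.03 (13) and -2.62 (14), and Shisa3 to -3.27 (13) and -4.54 (15).

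Over all genes, 1629 rose and 1052 fell from gd12 to gd14, 798 of them at least 2-fold (586 rises, 212 falls), and 4509 had an unadjusted p under 0.05. Stage ranges did not overlap for 2612 of the called genes and for 5380 of all 14338, where chance gives 10% for 3 arrays against 3. The simulation recovered 40.3%, 59.7% and 87.9% of genes changed 1.5-, 2- and 4-fold among 14338 genes, with 14 false calls. The count was 1780 without gd14 replicate 10. Median and mean of the hormone receptor list differed in sign.

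From gd14 to gd16 Dppa3 (1424295_at) went from 14000 ± 492 to 751 ± 611 (-4.45 ± 0.45, adjusted p = 2.08e-05), Sox2 (1416967_at) from 1390 ± 322 to 47.8 ± 35.4, near background (-4.45 ± 0.97, adjusted p = 0.00741), and Dppa5a from 7800 ± 2030 to 759 ± 288 (-3.36 ± 0.47, adjusted p = 0.000374). Nanog, a core pluripotency factor gene, changed by -2.40 ± 0.36. Of 25 measured members of the list, 10 fell and 0 rose, against 15 falls adjusted over the list alone (adjusted p = 1.21e-09, adjusted p = 0.406 with an estimated correlation). The epithelial cadherin gene Cdh1, on the mesonephros and duct list, fell from 1440 ± 133 to 116 ± 50.6 (-3.46 ± 0.43), as did Sall1 (-2.99 ± 0.49), among 4 falls and 0 rises of the 20 genes of that list, also adjusted over the list alone (adjusted p = 0.263).

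From gd14 to gd16 Hbb-y fell from 34100 ± 3470 to 3800 ± 4470 (-3.82 ± 0.46, adjusted p = 0.0001). Hba-x went from 6790 ± 1520 to 553 ± 572 (-4.00 ± 0.49, adjusted p = 0.000107). Hbb-y read 1292, 8957 and 1152 on gd16 replicates 7, 8 and 9, and without replicate 8 the changes of Hbb-y, Hba-x and Dppa3 were -4.77, -4.78 and -5.06. Of 12 erythroid genes 3 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.21). The rise was that of Alas2, the erythroid enzyme that starts heme synthesis (1.39 ± 0.36), which lost its call without gd16 replicate 8 or 9 or any 1 gd14 array (adjusted p = 0.0503 to 0.12). S100a8 (1419394_s_at) and S100a9, the calprotectin subunits of neutrophils, went up by 3.31 ± 0.49 (from 121 ± 98.9 to 1180 ± 262) and 3.13 ± 0.55. Dntt, the lymphocyte terminal transferase, rose by 3.18 ± 0.47, and Lyz2, a macrophage lysozyme gene, by 1.48 ± 0.31. The macrophage and leukocyte list had 4 rises and 0 falls among 21, against 6 rises adjusted over the list alone (adjusted p = 0.000293, adjusted p = 0.659 with an estimated correlation). S100a8 rose by 2.71 without gd14 replicate 11.

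Of 20 cholesterol synthesis genes, 8 rose and 0 fell from gd14 to gd16, against 9 rises adjusted over the list alone, such as Ebp (0.85 ± 0.16; adjusted p = 4.94e-06, adjusted p = 0.554 with an estimated correlation). Fetal Leydig genes gave 2 rises and 0 falls among 19, also adjusted over the list alone, namely Thbs2 (1.70 ± 0.26) and the lipoprotein receptor gene Scarb1 (0.84 ± 0.2, and 0.75 with adjusted p = 0.0666 without gd16 replicate 7; list adjusted p = 0.033, adjusted p = 0.673 with an estimated correlation). Cyp17a1 (17100 ± 765 and 26700 ± 2830, adjusted p = 0.317) and Star (3400 ± 403 and 6280 ± 2060, adjusted p = 0.414) were not called. Sertoli genes split, with 4 rises and 3 falls among 25 (5 and 3 adjusted over the list alone; adjusted p = 0.232): Cst12 rose by 2.29 ± 0.38 and Hsd17b1 by 2.18 ± 0.38, and the X-linked homeobox gene Rhox5 changed by -2.19 ± 0.4. Fetal male germ cell genes split too, with 3 rises and 5 falls among 23, also adjusted over the list alone (adjusted p = 0.321): Tdrd9, of the piRNA pathway, rose by 1.44 ± 0.29 and Tdrd5 changed by -1.92 ± 0.34. Dnmt3l rose from 1220 ± 221 to 2990 ± 324 (1.28 ± 0.33, adjusted p = 0.0211). Matrix genes gave 4 rises and 0 falls among 27 (5 rises adjusted over the list alone), with elastin, Eln, at 1.75 ± 0.36 (adjusted p = 0.00218, adjusted p = 0.715 with an estimated correlation). Skeletal and cardiac muscle genes gave 3 rises and 0 falls among 17 (4 rises adjusted over the list alone), with titin, Ttn, at 2.21 ± 0.43 (adjusted p = 0.00173, adjusted p = 0.412 with an estimated correlation). Dmkn and Hsd17b2 rose by 3.05 ± 0.38 and 3.08 ± 0.44.

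Over all genes, 773 rose and 715 fell from gd14 to gd16, 489 of them at least 2-fold (369 rises, 120 falls), with 3599 at an unadjusted p under 0.05, and stage ranges did not overlap for 1483 of the called genes. Chance gives 10% of all genes, and 5613 of 14338 were found. The simulation recovered 40.3%, 59.7% and 93.9% of genes changed 1.5-, 2- and 4-fold among 14338 genes, with 2 false calls. The count was 3020 in a fit of only these stages, 3292 with array weights, 606 without gd16 replicate 7, 494 without gd16 replicate 9, and 583, 920 and 858 without gd14 replicates 10, 11 and 12. Dnmt3l lost its call without any single array except gd14 replicate 12 (adjusted p = 0.0536 to 0.083), and Clca1 (3.22 ± 0.31) when dim probe sets were kept (0.44, adjusted p = 0.468). Median, mean or test differed in sign for the early gonad, meiosis, erythroid and immediate early lists.

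From gd16 to gd18 Tm7sf2, a sterol reductase gene, went from 1990 ± 414 to 447 ± 259 (-2.23 ± 0.32, adjusted p = 0.000649), Hsd17b7 from 1550 ± 37.1 to 620 ± 129 (-1.31 ± 0.16, adjusted p = 0.000243) and Msmo1 from 7600 ± 2060 to 3200 ± 624 (-1.23 ± 0.18, adjusted p = 0.000649). Of 20 cholesterol synthesis genes, 14 fell and 0 rose, against 17 falls adjusted over the list alone (adjusted p = 8.52e-20, adjusted p = 0.229 with an estimated correlation). Of 23 fetal male germ cell and piRNA genes, 10 fell and 0 rose, against 16 falls adjusted over the list alone (adjusted p = 4.72e-11, adjusted p = 0.378 with an estimated correlation). Among these, Tex14 went from 1960 ± 889 to 443 ± 62.4 (-2.01 ± 0.34) and Mov10l1, the piRNA helicase gene, from 2060 ± 221 to 655 ± 256 (-1.68 ± 0.32). Utf1 and Dnd1, of the pluripotency list, changed by -1.53 ± 0.28 and -2.30 ± 0.37, among 3 falls and 0 rises of 25 (5 falls adjusted over the list alone; adjusted p = 0.0345, adjusted p = 0.79 with an estimated correlation).

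Sertoli genes gave 3 rises and 2 falls among 25, but 10 rises and 2 falls adjusted over the list alone (adjusted p = 0.000121, adjusted p = 0.406 with an estimated correlation). Cst12 (1424627_at) rose from 4370 ± 1850 to 16100 ± 1590 (1.99 ± 0.38) and Shbg, sex hormone-binding globulin, from 441 ± 69.5 to 1510 ± 653 (1.66 ± 0.25). Leydig genes went both ways, with 2 rises and 2 falls among 19 (3 and 4 adjusted over the list alone; adjusted p = 0.737): Thbs2 rose by 1.49 ± 0.26 and Scarb1 changed by -1.08 ± 0.2. Their median and mean differed in sign. Cyp17a1 (26700 ± 2830 and 13000 ± 4940, adjusted p = 0.11) and Star (6280 ± 2060 and 2030 ± 1190, adjusted p = 0.114) were not called. Dpt (1418511_at), the matrix protein dermatopontin, rose from 310 ± 120 to 2910 ± 426 (3.21 ± 0.33, adjusted p = 3.12e-05), and Cyp27a1, a sterol hydroxylase gene, rose by 2.10 ± 0.27. The laminin gene Lama2 rose by 1.22 ± 0.19, the only call among 27 matrix genes, against 2 rises and 0 falls adjusted over the list alone (adjusted p = 0.000743, adjusted p = 0.673 with an estimated correlation).

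From gd16 to gd18 Hbb-y (1436823_x_at) fell from 3800 ± 4470 to 41.2 ± 9.54, near background (-5.25 ± 0.46, adjusted p = 8.5e-06), and Hba-x from 553 ± 572 to 30.8 ± 25.5, near background (-3.08 ± 0.49). Without gd16 replicate 8 these changes were -4.30 and -2.30. Of 12 erythroid genes 3 fell and 0 rose (3 and 2 adjusted over the list alone; adjusted p = 0.0335, adjusted p = 0.673 with an estimated correlation, adjusted p = 0.059 with the mean of all probe sets). Macrophage and leukocyte genes gave 1 rise and 0 falls among 21, C1qc at 1.45 ± 0.39, and 3 rises adjusted over the list alone (list adjusted p = 0.00113, adjusted p = 0.671 with an estimated correlation). C1qc lost its call without any 1 array except gd16 replicate 9 (adjusted p = 0.064 to 0.169). Immediate early and stress genes gave 2 rises and 1 fall among 20 (4 and 1 adjusted over the list alone; adjusted p = 0.0187, adjusted p = 0.565 with an estimated correlation). Crtam, of cytotoxic lymphocytes, and Adtrp changed by -2.82 ± 0.54 and -2.54 ± 0.44.

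Over all genes, 244 rose and 456 fell from gd16 to gd18, 201 of them at least 2-fold (82 rises, 119 falls), with 2548 at an unadjusted p under 0.05. Of the called genes 694, and of all 14338 genes 4120, had stage ranges that did not overlap, where chance gives 10%. The simulation recovered 31.3%, 68.7% and 87.9% of genes changed 1.5-, 2- and 4-fold among 14338 genes, with 8 false calls. The count was 1143 in a fit of only these stages, of which 564 rose, so the excess of falls was not seen there, and 1880 with array weights, and 189 and 267 without gd18 replicates 4 and 5, or 372, 195 and 441 without gd16 replicates 7, 8 and 9. Without gd18 replicate 4, Otx2 (2.41 ± 0.56), Kcng2 (2.19 ± 0.55), Rtl3 (2.01 ± 0.55), Lct (-2.60 ± 0.64), Svs4 (-2.37 ± 0.51) and Dnmt3l (-1.40 ± 0.33), all called with the full set, had adjusted p-values of 0.0855, 0.158, 0.113, 0.135, 0.0738 and 0.152. Calls were also lost without gd18 replicate 5 (Otx2 0.0823, Lct 0.0602, Rtl3 0.131, Svs4 0.0615, Dnmt3l 0.0881), gd18 replicate 6 (Rtl3 0.0731), gd16 replicate 7 (Otx2 0.0648, Kcng2 0.0721, Rtl3 0.141, Svs4 0.0563, Dnmt3l 0.0739), gd16 replicate 8 (Otx2 0.0638, Lct 0.144, Rtl3 0.192, Svs4 0.077, Dnmt3l 0.104) and gd16 replicate 9 (Kcng2 0.129), each an adjusted p. Kcng2 rose by 2.87 without gd16 replicate 8 (adjusted p = 0.0107).

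From gd18 to pnd2, across birth, Dnmt3l (1425035_s_at) went from 1260 ± 767 to 29.1 ± 19, near background (-4.55 ± 0.33, adjusted p = 4.72e-07), Utf1 from 772 ± 278 to 145 ± 43.8 (-2.22 ± 0.28, adjusted p = 0.000176) and Tdrd9 from 1630 ± 787 to 369 ± 103 (-2.02 ± 0.29, adjusted p = 0.000503). In the pluripotency list 5 of 25 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00714, adjusted p = 0.751 with an estimated correlation), and in the fetal male germ cell list 3 of 23 fell and 0 rose, against 4 falls and 2 rises adjusted over the list alone (adjusted p = 0.337). Tex13b rose by 2.44 ± 0.45, from 140 ± 70.8 to 805 ± 165, and Tex11, an X-linked meiosis gene, by 2.20 ± 0.4. Of 19 genes on the meiosis list 0 rose and 1 fell, against 1 rise and 1 fall adjusted over the list alone (adjusted p = 0.749). Spermatogonial genes, those of the male germ line stem and progenitor cells, gave 3 rises and 0 falls among 21, and 8 rises adjusted over the list alone (adjusted p = 0.0053, adjusted p = 0.378 with an estimated correlation), with the GDNF receptor genes Ret (1.51 ± 0.35) and Gfra1 (1.49 ± 0.44). Ret lost its call without pnd2 replicate 2 (adjusted p = 0.0727), gd18 replicate 5 (adjusted p = 0.0555) or gd18 replicate 6 (adjusted p = 0.0677), and Gfra1 without any 1 of the 6 arrays (adjusted p = 0.0772 to 0.144).

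Sertoli genes moved both ways, with 3 rises and 2 falls among 25, also adjusted over the list alone (adjusted p = 0.318): Cldn11, the tight junction claudin, rose from 252 ± 44.7 to 756 ± 90.4 (1.51 ± 0.3) and Fshr, the receptor of follicle-stimulating hormone, from 349 ± 46.6 to 792 ± 90.6 (1.13 ± 0.25), while Ropn1l fell from 1120 ± 324 to 104 ± 26 (-3.16 ± 0.26). Fshr lost its call without pnd2 replicate 2 (adjusted p = 0.0543) or gd18 replicate 6 (adjusted p = 0.0563). Amh (2350 ± 828 and 2390 ± 471, adjusted p = 0.944) and Dhh (4450 ± 734 and 5670 ± 460, adjusted p = 0.307) were not called. Leydig genes gave 1 rise and 3 falls among 19, also adjusted over the list alone (adjusted p = 0.538). Cyp17a1 fell from 13000 ± 4940 to 4000 ± 2150 (-1.78 ± 0.38, adjusted p = 0.00931), and without pnd2 replicate 2, which read 1914 against 3882 and 6216 in replicates 1 and 3, its change was -1.33 (adjusted p = 0.0522). Endothelial genes gave 7 falls and 0 rises among 20, against 9 falls adjusted over the list alone, with Sox17 at -1.32 ± 0.22 and the VEGF receptor gene Flt1 at -1.43 ± 0.27 (adjusted p = 0.000266, adjusted p = 0.665 with an estimated correlation). Imprinted genes gave 6 falls and 0 rises among 24, against 8 falls adjusted over the list alone, with Grb10 at -0.76 ± 0.1 (-0.66 and not called with the mean of all its probe sets, adjusted p = 0.102; list adjusted p = 8.56e-05, adjusted p = 0.565 with an estimated correlation). Cell division genes gave 3 rises and 1 fall among 27 (5 and 2 adjusted over the list alone) (adjusted p = 0.00954, adjusted p = 0.754 with an estimated correlation). Among the rises, Mcm5, a replication licensing gene (0.38 ± 0.11), lost its call without any 1 of the 6 arrays (adjusted p = 0.0847 to 0.124).

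Among erythroid genes, Alas2 (1451675_a_at) went from 2120 ± 1100 to 187 ± 28.1 (-3.23 ± 0.36, adjusted p = 5.95e-05), among 4 falls and 0 rises of 12 erythroid genes, 6 falls adjusted over the list alone (adjusted p = 0.00288, adjusted p = 0.582 with an estimated correlation). The band 3 gene Slc4a1 read 190, 1839 and 117 on gd18 replicates 4, 5 and 6, and its change of -2.80 ± 0.61 was -1.65 without replicate 5 and -3.52 without replicate 6. Falls were also called for Dscaml1 (-3.70 ± 0.34), Foxa1 (-3.54 ± 0.55), Irs4 (-3.46 ± 0.39) and Shox2 (-3.18 ± 0.78), and rises for Glb1l3 (2.30 ± 0.33), Etv4 (2.18 ± 0.47), Cirbp (2.00 ± 0.2), a cold-inducible RNA-binding protein gene, and Acaa1b (1.97 ± 0.44).

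Over all genes, 364 rose and 754 fell from gd18 to pnd2, 349 of them at least 2-fold (44 rises, 305 falls), with 3336 at an unadjusted p under 0.05. Of the called genes 1107, and of all 14338 genes 4801, had stage ranges that did not overlap, where chance gives 10%. The simulation recovered 35.8%, 55.2% and 86.4% of genes changed 1.5-, 2- and 4-fold among 14338 genes, with 0 false calls. The count was 2283 with array weights, 589, 564 and 604 without pnd2 replicates 1, 2 and 3, and 673 and 437 without gd18 replicates 5 and 6. Acaa1b lost its call without gd18 replicate 6 (1.61, adjusted p = 0.0694) and Shox2 without pnd2 replicate 1 (adjusted p = 0.0613), pnd2 replicate 3 (adjusted p = 0.0635), gd18 replicate 4 (adjusted p = 0.0577) or gd18 replicate 6 (adjusted p = 0.0602). Medians, means or tests differed in sign for the Sertoli, macrophage, cell cycle inhibitor, hormone receptor, glutathione and sex-linked lists.

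**Figure D3:**
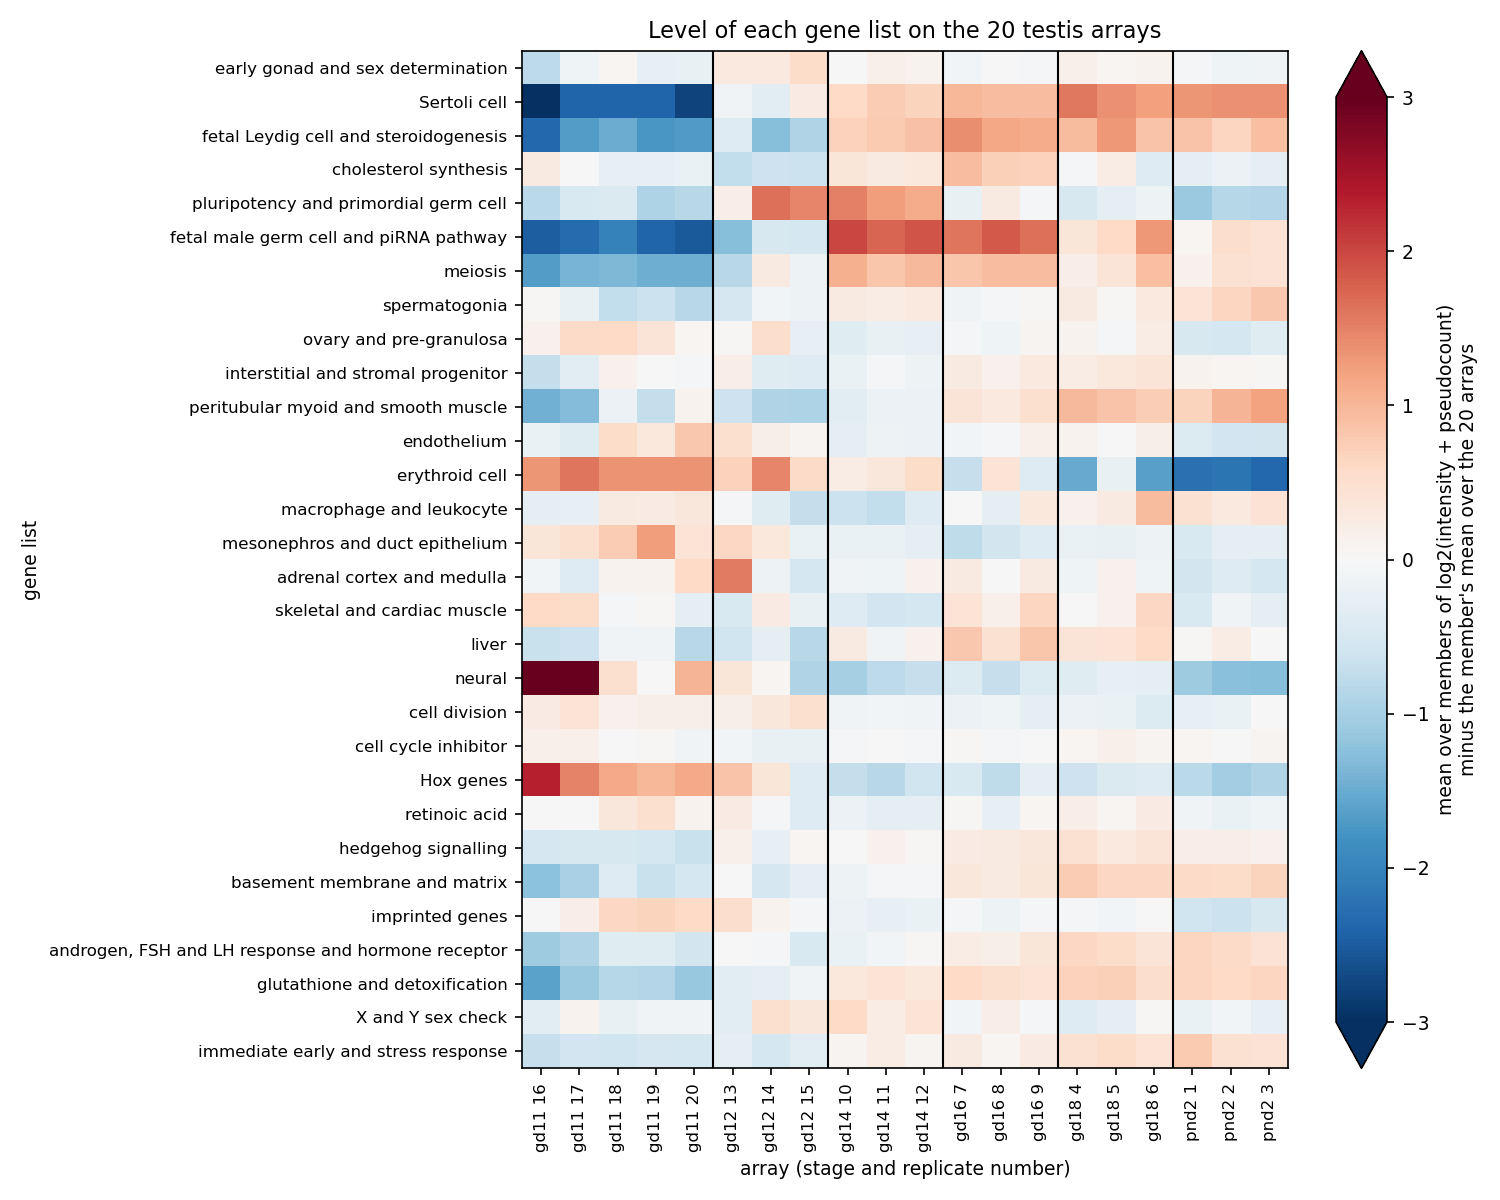
Colour gives the level of each of the 30 gene lists (vertical axis) on the 20 testis arrays (horizontal axis, ordered by stage), as the mean over members of log2(intensity + 22.4) minus each member's mean over the 20 arrays. Sertoli genes were lowest on the 5 gd11 arrays, the erythroid list was lowest at pnd2, and gd11 replicates 16 and 17 stood out in neural genes and gd12 replicate 13 in adrenal genes.

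Over the whole span from gd11 to pnd2, Cst12 (1424627_at), a cystatin gene, went from 38 ± 29.6, near background, to 19500 ± 850 (8.46 ± 0.34, adjusted p = 4.72e-13). Also from near background, Defb19 went from 49.3 ± 27.5 to 13000 ± 2240 (7.61 ± 0.31), the glutathione transferase gene Gstm6 from 32.8 ± 27.1 to 9130 ± 763 (7.51 ± 0.29) and Cyp17a1 from 6.78 ± 2.14 to 4000 ± 2150 (6.96 ± 0.34). Dpt and Kazald1, of the matrix, rose by 7.01 ± 0.29 and 6.86 ± 0.27. Hbb-y (1436823_x_at) fell from 34100 ± 2490 to 4.92 ± 6.22, near background (-10.31 ± 0.41, adjusted p = 4.72e-13), Hbb-bh1 by a log2 change of -9.53 ± 0.37 and Hba-x by -8.98 ± 0.44. Hmga2 (1450780_s_at), a chromatin protein gene of embryonic growth, fell from 14200 ± 3670 to 120 ± 29.5 (-6.62 ± 0.19, adjusted p = 1.26e-14).

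Of 25 Sertoli genes 22 rose and 1 fell (adjusted p = 1.3e-16, adjusted p = 0.0527 with an estimated correlation). Of 19 Leydig genes 15 rose and 1 fell (adjusted p = 4.69e-08, adjusted p = 0.378 with an estimated correlation), the counts adjusted over the list alone being the same for both. Fetal male germ cell genes gave 21 rises and 0 falls among 23 (adjusted p = 4.74e-12, adjusted p = 0.378 with an estimated correlation). Meiosis genes gave 15 and 0 among 19 (adjusted p = 3.9e-06, adjusted p = 0.406 with an estimated correlation) and spermatogonial genes 14 and 1 among 21 (adjusted p = 0.00118, adjusted p = 0.378 with an estimated correlation), all the same adjusted over the list alone. Matrix genes gave 18 rises and 1 fall among 27, also adjusted over the list alone, with Eln at 5.06 ± 0.32 (adjusted p = 4.49e-07, adjusted p = 0.565 with an estimated correlation). Smooth muscle genes gave 11 rises and 0 falls among 17, also adjusted over the list alone, with the smooth muscle myosin gene Myh11 at 4.18 ± 0.33 (adjusted p = 0.000341, adjusted p = 0.582 with an estimated correlation). Their median change of 1.76 was 1.13 without gd11 replicates 16 and 17, with 10 rises and 2 falls. Stra8 rose from 52.8 ± 30.1, near background, to 526 ± 312 (2.81 ± 0.43, adjusted p = 2.38e-05). Hox genes gave 20 falls and 1 rise among 27, also adjusted over the list alone, with Hoxa9 at -4.95 ± 0.43 (adjusted p = 4.69e-08, adjusted p = 0.406 with an estimated correlation). Neural genes gave 11 falls and 0 rises among 14, also adjusted over the list alone, with Isl1 at -5.57 ± 0.76 and Nefl at -5.54 ± 0.77 (adjusted p = 0.00068, adjusted p = 0.671 with an estimated correlation). The neural median of -3.07 was -1.77 without gd11 replicates 16 and 17, with 9 falls and 1 rise. Nefl read 17280 and 12120 on these arrays, and Isl1 was at -6.17 without gd11 replicate 19. Erythroid genes gave 10 falls and 1 rise among 12, 11 falls adjusted over the list alone (adjusted p = 3.77e-05, adjusted p = 0.406 with an estimated correlation). Cell division genes gave 15 falls and 0 rises among 27, also adjusted over the list alone, with Mki67 at -0.45 ± 0.1 (adjusted p = 0.000743, adjusted p = 0.671 with an estimated correlation). Endothelial genes gave 13 falls and 4 rises among 20 (14 and 4 adjusted over the list alone; adjusted p = 0.00954, adjusted p = 0.764 with an estimated correlation). Mesonephros and duct genes gave 11 falls and 3 rises among 20, also adjusted over the list alone (adjusted p = 0.0365, adjusted p = 0.614 with an estimated correlation).

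In all, 3471 genes rose and 3494 fell from gd11 to pnd2, 2688 of them at least 2-fold (1610 rises, 1078 falls), with 7782 at an unadjusted p under 0.05, and 5952 of the called genes had stage ranges that did not overlap. The simulation recovered 38.8%, 73.1% and 95.5% of genes changed 1.5-, 2- and 4-fold among 14338 genes, with 4 false calls. For 154 called genes, another called probe set of the gene moved the opposite way. Medians, means or tests differed in sign for the early gonad, liver, retinoic acid and hedgehog lists.

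**Figure D4:**
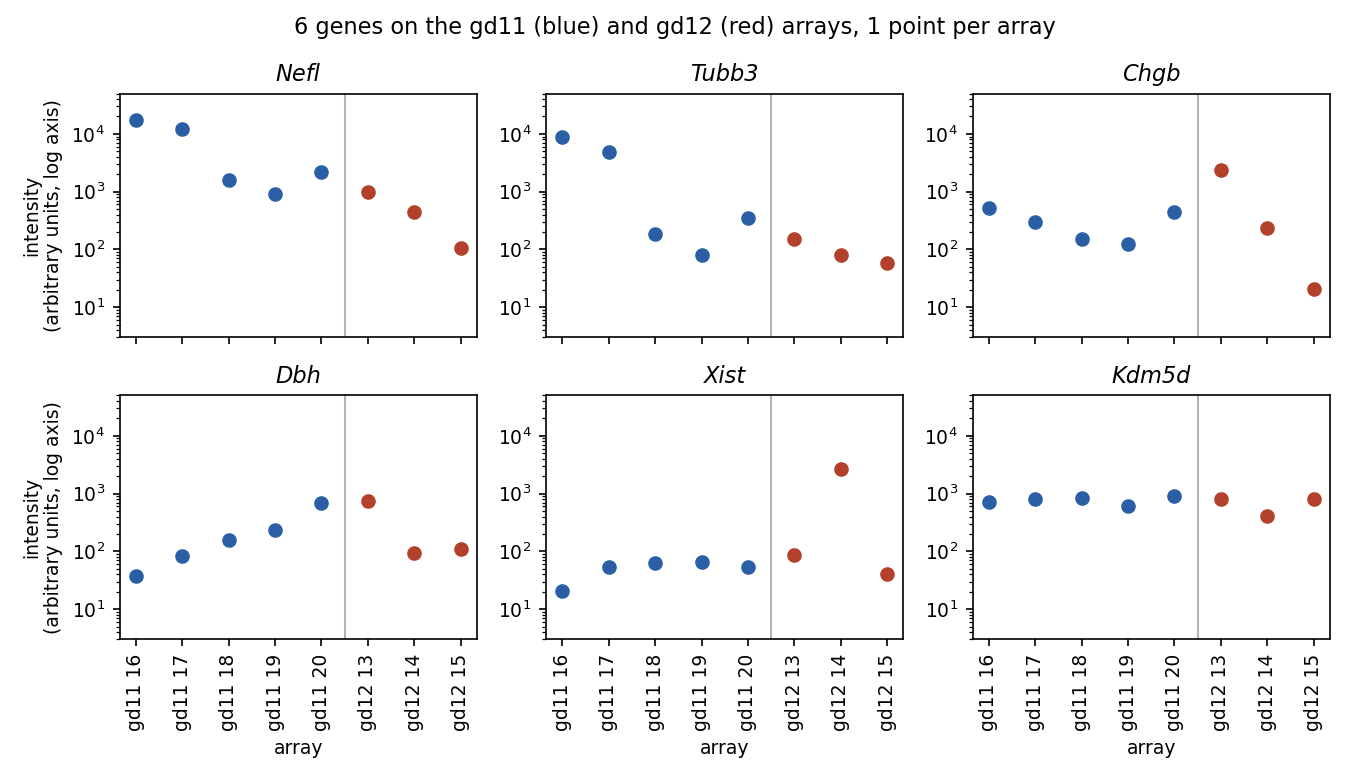
Each panel shows the intensity of 1 gene (vertical log axis, arbitrary units) on the 5 gd11 arrays (blue) and the 3 gd12 arrays (red), with 1 point per array. The neurofilament gene Nefl read 17280 and 12120 on gd11 replicates 16 and 17, Chgb 2404 on gd12 replicate 13, and Xist 2616 on gd12 replicate 14, where the Y-linked Kdm5d read 406.

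The single array of whole newborns has no replicate and entered no test, so the differences below describe that array alone. Where either value lay near background, the difference depends on the added constant. Compared with it, the pnd2 testis mean was at least 4-fold higher for 600 and at least 4-fold lower for 1124 of 14338 genes. The filter and the choice of probe sets used the testis arrays only. Genes of the newborn body that were dim in testis are thus left out of both counts. Cst12 read 19500 ± 850 in the testis and 29.3 in the reference, Amhr2, the receptor of anti-Müllerian hormone, 7750 ± 176 and 18.3, and Dazl 4970 ± 1030 and 33, the reference values being near background. Near background in the testis were Apoa1, an apolipoprotein of liver and gut (24.5 ± 22.1 and 33800), Myl1, of skeletal muscle (17.7 ± 13.5 and 28400), Ctrb1, of the pancreas (8.7 ± 1.39 and 22500), and Alb, serum albumin (43.1 ± 50.4 and 34600). The median difference was 3.82 for Sertoli genes, 2.93 for fetal male germ cell genes and 1.40 for cell division genes, each above all 10000 random lists. It was -7.25 for liver, -7.06 for skeletal muscle, -3.27 for neural, -3.24 for erythroid, -1.86 for macrophage and -1.48 for mesonephros and duct genes, each below all of them.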

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

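The tests of tissue sources and of array-wide differences below were chosen only after the results were seen.

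In groups of 5 arrays, an array was singled out when its gap to the nearest other array took up most of the range of the group. Gap and range were taken on the log2 scale used for the tests. Gene values below are printed as linear intensities, on which the same ratios differ. List levels are already on the log2 scale. Of 215 levels tested at gd11, 16 had such an array, where chance flags about 1 in 20 (10.8 levels). Replicate 16 held 9 of them, replicate 17 held 3 and replicate 19 held 4. Replicate 16 was lowest for Aldh1a1 (intensity 121 against 750 to 1420 on the other arrays, gap over range 0.73), Amhr2 (508 against 1960 to 3370, 0.711), Dcn (498 against 1550 to 2380, 0.725), Gstm1 (662 against 1330 to 1650, 0.766), Gstm2 (418 against 1260 to 1890, 0.725) and Xist (20.7 against 52.9 to 64.4, 0.797). It was also lowest for the level of the fetal Leydig and steroidogenesis list (-2.37 against -1.74 to -1.5, 0.724), and highest for Amh (30.5 against 2.89 to 7.45, 0.775) and Hsd17b7 (1150 against 728 to 805, 0.783). Replicate 17 was highest for Dpt (23.7 against 4 to 8.13, 0.739), Hormad1 (33.4 against 0.48 to 6.56, 0.736) and the level of the erythroid list (1.6 against 1.33 to 1.35, 0.94). Replicate 19 was highest for Dnmt3l (21.8 against 6.82 to 8.22, 0.887), Fshr (30.7 against 3.26 to 7.92, 0.771), Gdnf (157 against 2.86 to 8.2, 0.902) and Spo11 (24.5 against 3.94 to 7.65, 0.772). Amh, Dnmt3l, Dpt, Fshr, Hormad1, Spo11 and Xist lay near background on all 5 arrays and Gdnf on all but replicate 19, so their ranks are mostly those of background signal.

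Neural genes stood high in gd11 replicates 16 and 17, where all 14 measured members of the neural list had their 2 highest gd11 intensities. That count is the pattern itself, so neural tissue dissected with the gonads may be its source but was not tested apart from it. The most abundant were Nefl (17280 and 12120 against 914 to 2203) and Stmn2 (11520 and 5780 against 257 to 467), no member is held by another list, and 5 of 14 lay above background at every stage from gd14. A lower share of gonad cells would raise the markers of all other cells alike only if no single tissue took their place. Against the gd11 median, the neural list lay at 2.83 (quartiles 2.1 to 4.3) and 2.25 (quartiles 1.26 to 3.3) in the 2 arrays. In all 5 lists of other cells with enough members above background, the upper quartile lay below the neural lower quartile in both arrays. The neural list was chosen for standing high, so this ranking is partly the choice itself and decides nothing alone. The macrophage list lay at -0.45 (quartiles -0.63 to -0.22) and -0.37 (quartiles -0.52 to -0.19). The mesonephros list lay at -0.75 (quartiles -1.37 to -0.01) and -0.27 (quartiles -0.52 to 0). That neither list rose argues against an even rise of all other cells. The highest, skeletal muscle, lay at 0.59 (quartiles 0.05 to 1.03) and 0.41 (quartiles 0.03 to 0.9). A lower share of gonad cells beside 1 added tissue stays open. The early gonad, Sertoli and Leydig lists lay at -0.8, -0.38 and -0.33 in replicate 16, but at 0.11, 0.18 and 0 in replicate 17. An array-wide difference in scale or background was argued against by the neural deviation of at least 2.21 in both arrays after quantile normalization. No biological explanation was tested, because the design gives none within a stage.

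Xist stood at 2616 in gd12 replicate 14, against 87.7 and 40.6 in replicates 13 and 15, which may come from XX gonads in a pool of 5. The Y-linked genes Kdm5d (-0.98), Uty (-0.7) and Eif2s3y (-0.22) were lower there by a mean log2 difference of -0.63. Their mean differed by 0.16 between replicates 13 and 15, which is not the spread of single Y-linked genes. Usp9y and Sry, also Y-linked, were not lowest in replicate 14 but lay between replicates 13 and 15. The change of Usp9y from gd12 to gd14 was 3.43, but 2.76 without replicate 13 and 4.09 without replicate 15. Of 18 ovary genes, 12 were highest in replicate 14. An all-female sample was argued against by the 3 Y-linked genes, the lowest of which stood at percentile 62.9 of that array. The limit for this was set after the results were seen. No female array shows where these probe sets lie without a Y chromosome. No biological explanation was tested, because the design gives none within a stage.

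Adrenal genes stood high in gd12 replicate 13, where all 13 measured members of the adrenal list were highest among the gd12 arrays. That count is the pattern itself, so adrenal or sympathetic tissue in the pool may be its source but was not tested apart from it. The most abundant read 2404 (Chgb), 750 (Dbh) and 451 (Th) there, against 20.3 to 239, 93.4 to 108 and 57.6 to 104 in the other two arrays, 3 of the 13 genes are held by another list, and 5 of 13 lay above background at every stage from gd14. In 3 of 5 lists of other cells, the upper quartile lay below the adrenal lower quartile (median difference 2.11, quartiles 0.99 to 2.24). They were the erythroid (-0.47, quartiles -0.61 to -0.16), skeletal muscle (-0.48, quartiles -0.69 to -0.24) and macrophage lists (0.53, quartiles 0.33 to 0.8). The adrenal list was chosen for standing high, so this ranking is partly the choice itself and decides nothing alone. Against the gd12 median the erythroid and skeletal muscle lists lay at 0 and -0.04, which argues against an even rise of all other cells. The mesonephros (0.88, quartiles -0.06 to 1.4) and neural lists (0.85, quartiles 0.27 to 1.27) were not set apart, so other tissue beside the adrenal stays open. A lower share of gonad cells beside such tissue stays open too. Against the gd12 median, the same array also stood low in the pluripotency (-1.37) and fetal male germ cell lists (-0.76) and high in Hox genes (0.55), while the Leydig list was at 0.05. Another age of the pool was not tested as the source and stays open. No biological explanation was tested, because the design gives none within a stage.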

How the results depend on the processing

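Leaving out arrays that stood apart was chosen only after the data were seen, and all other alternatives were planned. With a threshold of at least 2-fold the counts were 952 (gd12 against gd11), 798 (gd14 against gd12), 489 (gd16 against gd14), 201 (gd18 against gd16), 349 (pnd2 against gd18), 2688 (pnd2 against gd11) and 4661 (over all stages), fewer by construction. With only the stages compared in the fit, which takes the spread from their arrays alone, the gd11 to gd12 count went from 3067 to 1286. That of gd14 to gd16 went from 1488 to 3020, and that of gd16 to gd18 from 700 to 1143. With array weights it was 3292 from gd14 to gd16, 1880 from gd16 to gd18 and 2283 from gd18 to pnd2, and without gd12 replicates 13 and 14 it was 943 from gd12 to gd14, and the cause was not tested. Leaving out 1 array gave 1671 to 3161, 1780 to 2158, 494 to 1226, 189 to 855 and 437 to 785 genes for the adjacent comparisons in order of age, 5965 to 6973 from gd11 to pnd2 and 9306 to 10015 over all stages. Of the list shifts, 71 were called at the preset correlation, 1 with an estimated correlation, 57 by fry, 69 after quantile normalization and 68 with the mean of all probe sets. List shifts that were not called at first and were called in the opposite direction without gd11 replicates 16 and 17 and gd12 replicates 13 and 14, all from gd11 to gd12, were those of the interstitial (adjusted p = 0.0259), endothelium (adjusted p = 0.00495) and adrenal lists (adjusted p = 0.0341), with endothelium also without gd11 replicates 16 and 17 alone (adjusted p = 0.0229), and the cause was not tested. Leaving out these 4 arrays leaves 1 gd12 array, so no conclusion is drawn from the adjusted p-values of that run. Its interstitial, endothelium and adrenal medians were -0.54, -0.27 and -0.45, against 0.1, 0.09 and 0.38 with all arrays. The run without gd11 replicates 16 and 17 alone kept all gd12 arrays, and its endothelium median was -0.26. Without the 4 arrays the medians of the spermatogonia, ovary, mesonephros, cell division and retinoic acid lists were 0.19, -0.36, -0.79, 0.34 and -0.66. With all arrays they were 0.26, -0.44, -0.8, 0.13 and -0.28. Gained in the same direction without gd11 replicates 16 and 17 alone were the spermatogonia (adjusted p = 0.0162), mesonephros (adjusted p = 0.0455) and cell division shifts (adjusted p = 0.0162). Of the named gene and comparison pairs, 525 of 586 were called, 315 of these kept the call in every alternative run and 210 lost it in at least 1, and no called change reversed. Runs that left 1 gd12 array are included. In 52 runs a pair not called in the main fit was called. Genes near background limit what can be seen, since their folds shrink with the added constant.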

Other observations

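Splits of the arrays were planned, and the array values of single genes below were chosen only after they were seen.

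Retinoic acid genes moved both ways from gd11 to gd12, with 2 rises and 4 falls among 16 (3 and 4 adjusted over the list alone; adjusted p = 0.246 by camera). Its median change was -0.28 with all arrays. Without gd12 replicates 13 and 14, which leaves 1 gd12 array, the median was -0.47, and -0.66 without gd11 replicates 16 and 17 as well. Aldh1a1, a retinaldehyde dehydrogenase gene, rose from 856 ± 487 (SD, n = 5) to 10700 ± 1900 (n = 3; log2 change 3.94 ± 0.45 SE), and Cyp26b1, which degrades retinoic acid, rose from 399 ± 145 to 1630 ± 532 (1.99 ± 0.23). Crabp2, a retinoic acid-binding protein gene, fell from 5380 ± 3500 to 962 ± 404 (-2.34 ± 0.36). Hedgehog genes gave 4 rises and 4 falls among 13, also adjusted over the list alone (adjusted p = 0.443), with the receptor gene Ptch1 going from 3090 ± 433 to 6280 ± 1320 (1.01 ± 0.12). Glutathione and detoxification genes gave 10 rises and 2 falls among 25, also adjusted over the list alone (adjusted p = 7.48e-05, adjusted p = 0.406 with an estimated correlation), with Gstm2 at 3.12 ± 0.29 and Gstm1 at 2.62 ± 0.21. Their median change of 0.47 was 0.17 without gd11 replicates 16 and 17 (adjusted p = 8.71e-05). Interstitial and stromal progenitor genes gave 5 rises and 5 falls among 22, also adjusted over the list alone (adjusted p = 0.889), with Lhx2 at -1.68 ± 0.24. Cell cycle inhibitor genes gave 1 rise and 5 falls among 16 (1 and 7 adjusted over the list alone; adjusted p = 0.0319, adjusted p = 0.406 with an estimated correlation), with a median of -0.28. That shift was not called without gd12 replicate 14 (adjusted p = 0.0697) or gd11 replicates 16 and 17 (median -0.05, adjusted p = 0.22), nor with the mean of all probe sets (adjusted p = 0.152). Without gd12 replicates 13 and 14, which leaves 1 gd12 array, its median was -0.23, and 0 without gd11 replicates 16 and 17 as well. X- and Y-linked genes gave 2 rises and 1 fall among 7 (3 and 1 adjusted over the list alone; adjusted p = 0.454).

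Over the span from gd11 to pnd2, hormone receptor genes gave 7 rises and 2 falls among 11 (7 and 3 adjusted over the list alone; adjusted p = 0.0343, adjusted p = 0.622 with an estimated correlation), with Fshr going from 11.3 ± 11, near background, to 792 ± 90.6 (4.64 ± 0.23). That shift was not called without gd11 replicates 16 and 17 (adjusted p = 0.0997). Immediate early and stress genes gave 12 rises and 1 fall among 20, also adjusted over the list alone (adjusted p = 0.00113, adjusted p = 0.406 with an estimated correlation), with the heat shock gene Hspa1a at 4.06 ± 0.36 and Egr1 at 3.12 ± 0.24. Ovary and pre-granulosa genes gave 8 falls and 2 rises among 18, also adjusted over the list alone (adjusted p = 0.0431, adjusted p = 0.591 with an estimated correlation, adjusted p = 0.0522 after quantile normalization), with Wnt4 at -2.49 ± 0.28 and Lef1 at -2.35 ± 0.17. Liver genes gave 4 rises and 0 falls among 11, also adjusted over the list alone (adjusted p = 0.454), with Ahsg at 2.49 ± 0.27. Imprinted genes gave 16 falls and 4 rises among 24 (17 and 4 adjusted over the list alone; adjusted p = 0.000237, adjusted p = 0.582 with an estimated correlation), with Asb4 at -5.36 ± 0.44.

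The splits ask only whether stage labels assigned at random give such counts, not whether dissection or batch is a source. For gd12 against gd11 only the real split, 1 of 56, gave as many genes (3067, and 1764 in the highest other split), as for pnd2 against gd11 (6965 and 2986). In both, the highest other split set gd11 replicates 16, 17 and 19 against the remaining arrays of the 2 stages. A grouping with the neural-high arrays on 1 side thus also called many genes. Over all stages 1 of 100 groupings, the real one, gave 9790 genes and the highest other 109. The 10 splits of 3 arrays against 3 are too few for a share under 0.05: the real split and the highest other gave 2681 and 1 (gd14 against gd12), 1488 and 0 (gd16 against gd14), 700 and 0 (gd18 against gd16), and 1118 and 1 (pnd2 against gd18).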
